A study of Mus musculus with 8 samples.

How the data were processed

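Nuclei of the prefrontal cortex of H2B-TRAP mice aged 3 to 4 months were profiled by droplet-based single-nucleus RNA sequencing 2 weeks after a retrograde virus carrying Cre was injected into the DMS or the MD. Per the labels' protocols, dorsal and ventral tissue was dissected under a fluorescent stereoscope and pooled by target and subregion, with the sexes kept apart, and nuclei stained with NucBlue were sorted to remove those of poor quality. The series text describes a sort for mCherry-positive nuclei, and the sources used here do not settle which gate was applied. Nothing in the labels says that the pools hold separate animals beyond their being separate pools, or whether dorsal and ventral pools share mice.

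Per the submitters' processing notes, reads were processed with Cell Ranger on mm10, with no version given. The deposited matrices hold counts of unique molecular identifiers per gene and barcode, which the authors made with Cell Ranger and did not normalize. The filtered matrix of each library was used throughout. A second deposited matrix of whole-number counts exists for each library, and how it was made is not given in the sources used here. For barcodes present in both, no entry of the second matrix was above that of the filtered one, and 1.20 to 4.27% of the counts were gone. It was used as an alternative. No reporter or virus sequence is among the 32285 features. Gene positions came from GENCODE M21 (GRCm38), which held 32158 of the features (99.6%).

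The choice of tests, gene lists, marker lists, filters, the rule for named genes and the first set of alternatives was made before the data were examined. Of 69411 barcodes, those with at least 500 genes and at most 5% mitochondrial counts were kept, which removed 868. Doublets were scored in each library with Scrublet (30 components), and the highest-scoring share, which grew by 0.8% for each 1000 nuclei in the library, was removed, in total 5068, which left 63475 nuclei. With scanpy 1.11.5, 3000 variable genes and 40 principal components were used to build a graph of 20 neighbours, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 gave 33 clusters. Clusters were named from the marker lists. A glutamatergic class needed a score of at least 0.5, a lead of at least 0.3 over the second list and 3 markers detected at 5 CPM or more. The cluster's 10 leading genes were also not to point to another list. IT clusters that failed a step but led the lists of other types by at least 0.5 were left without a layer. Other classes needed a score of at least 2 and 3 such markers. Clusters with over 50% doublets or under 20 nuclei were given no class. The thresholds for naming were set after marker scores and shares of clusters had been seen but before any test of genes between groups. An earlier score minimum of 0.4 changed no cluster's class, and an earlier marker minimum of 10 CPM left cluster 2, here L6 IT-like, without a resolved layer.

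The classes tested were L2/3 IT-like (cluster 1, 7342 nuclei), L6 IT-like (cluster 2, 5108), L5 PT-like (clusters 6, 7, 13 and 15, 21457), L5/6 NP-like (cluster 17, 894) and L6 CT-like (clusters 14 and 19, 5070), each with at least 30 nuclei in every library. IT clusters 0, 3, 11, 16 and 20 (13538 nuclei) could not be assigned to a layer and were not tested. Cluster 19 was kept in the L6 CT-like class by the naming rule, but 57.8% of it fell in clusters without a class name at resolution 2. The smallest summed library had 59 nuclei and 173935 counts in L2/3 IT-like, 35 nuclei and 177136 counts in L6 CT-like and 54 nuclei and 146915 counts in L5/6 NP-like nuclei.

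Shares of glutamatergic nuclei were compared between 4 and 4 libraries with an exact two-sided permutation test over all 70 assignments (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), with Benjamini-Hochberg adjustment over 10 tests. For genes, counts were summed per library and class and tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr), with sex, subregion and target as terms and 4 residual degrees of freedom. The interaction of subregion and target was tested in a model with 3 residual degrees of freedom. A gene was called at an adjusted p (Benjamini-Hochberg within class and contrast) under 0.05. Log2 fold changes are DMS minus MD, dorsal minus ventral and female minus male, and the SE is the absolute log2 fold change divided by the square root of the F statistic. The replicate number names only the sex, and the correlation across genes between the groups' replicate differences lay between -0.169 and 0.219, so that pools of the same number were not treated as pairs beyond the sex term. Genes are not independent replicates in that correlation.

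Gene lists (22 of function and 26 of cell types) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and again with an estimated one, for lists with at least 3 members tested. The calls with a preset correlation numbered 27 and those with an estimated one 0. The 192 named genes were, for each class and the contrasts of target and subregion, the 3 largest changes in each direction among called genes with a mean log2 CPM of at least 4 and a symbol that is not a placeholder, the 5 genes called in most classes, and up to 4 called members of each list. The 5 smallest p of the interaction, the sex-linked genes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y, 5 autosomal genes called between the sexes and Rpl10a were added. Frmpd4 was chosen after its values were seen.

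The test was tried on simulated data in which 200 genes were changed. These were drawn only from genes above a minimum mean count, so recovery may be lower among all genes tested. Counts were drawn with the trended dispersion, without a spread of each gene's own. GABAergic counts were drawn with the dispersion of the projection class. For DMS against MD, edgeR recovered between 95.5 and 100% of 4-fold and between 69.4 and 85.0% of 2-fold changes. For the interaction it recovered between 50.8 and 81.0% of 4-fold changes, and the share of false calls reached 13.0% in L2/3 IT-like nuclei. For the difference from GABAergic nuclei it recovered between 9.46 and 16.9% of 1.5-fold, 57.1 and 77.4% of 2-fold and 97.2 and 100% of 4-fold changes.

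Alternatives chosen in advance were no gene filter, RLE normalization, the Wald test of DESeq2 1.42.0, the second matrix, barcodes present in both matrices, at least 1000 genes and at most 1% mitochondrial counts, no removal of doublets, resolution 2 (49 clusters), shares of all kept nuclei, no sex term, an estimated correlation for the lists, and leaving out each library. Added after the data were seen were the difference from GABAergic nuclei of the same library (1709 nuclei), single clusters of the L5 PT-like and L6 CT-like classes, the earlier naming rules, and a permutation test of the dorsal and ventral shares within each target. The values are not corrected for free RNA. Python 3.11.15, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used.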

Results

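Single-nucleus RNA sequencing was used to profile neurons of the mouse prefrontal cortex (PFC) that project to the dorsomedial striatum (DMS) or to the mediodorsal thalamus (MD). A retrograde virus that delivers Cre recombinase was injected into one of the targets in mice of the H2B-TRAP line, whose Cre-dependent nuclear mCherry marks the neurons that take the virus up at their axon terminals. Tissue of the dorsal or the ventral PFC was then pooled, with females and males kept apart. The 8 libraries form 4 groups of 2, dorsal DMS, dorsal MD, ventral DMS and ventral MD. Replicate 1 of each group was female and replicate 2 male, so that each target, each subregion and each sex is represented by 4 libraries. Each library was one pool of tissue. No 2 pools shared target, subregion and sex, so the spread between like pools was not measured. The p-values of the gene tests measure the spread between pools together with any interaction of these factors left out of the model. The permutation tests of shares had no term for the factors not compared, whose differences add to their spread. The deposited matrices held between 4827 barcodes in the ventral MD female library and 12410 in the ventral DMS male library, and total counts of 17327450 to 46195711 per library. After filtering, 4602 to 11061 nuclei per library were kept, with a median of 2860 to 4411 unique molecular identifiers (UMIs) per nucleus. Of the 63475 kept nuclei, 55969 fell in glutamatergic clusters.

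Nuclei from DMS libraries were mostly of intratelencephalic (IT) type, the cortical neurons that project within the telencephalon, and nuclei from MD libraries were mostly of the pyramidal tract (PT) and corticothalamic (CT) types. L5 PT-like nuclei made up 67.7% ± 11.2 of the glutamatergic nuclei in MD libraries and 15.2% ± 5.41 in DMS libraries (SD, n = 4 each). L6 CT-like nuclei made up 18.5% ± 8.26 in MD and 2.04% ± 1.28 in DMS libraries. L2/3 IT-like nuclei made up 21.5% ± 5.02 in DMS and 2.70% ± 1.37 in MD libraries, and L6 IT-like nuclei 13.4% ± 3.51 and 3.52% ± 1.43. IT clusters whose layer was not resolved added 39.8% ± 3.75 in DMS and 3.76% ± 1.36 in MD libraries, which brought all IT clusters to 74.7% ± 9.74 and 9.98% ± 3.71. Clusters of glutamatergic nuclei that received no class name held 6.66% ± 3.48 in DMS and 2.00% ± 0.340 in MD libraries. This difference and the size of the PT share depended on the clustering. With finer clustering 96.1% of the nuclei of cluster 13, one of the 4 L5 PT-like clusters, fell in clusters without a class name. Such clusters then held 8.08% ± 8.42 in DMS and 23.3% ± 8.61 in MD libraries, and L5 PT-like nuclei 10.4% ± 2.24 and 45.3% ± 8.04. Of cluster 2, the L6 IT-like class, 55.5% then had no resolved layer, and L6 IT-like nuclei made up 5.18% ± 2.02 in DMS and 2.52% ± 1.33 in MD libraries.

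For each of L2/3 IT-like, L6 IT-like, L5 PT-like and L6 CT-like nuclei, the 4 DMS and the 4 MD libraries did not overlap, though for L6 IT-like nuclei they did with finer clustering (lowest DMS library 2.71%, highest MD library 4.49%). The exact two-sided permutation test gave p = 0.0286 for each, the smallest value that the 70 assignments of 4 against 4 libraries can give. The adjusted p was 0.0714 over the 10 comparisons of shares by this permutation test, so none passed the correction. The near-projecting L5/6 NP-like nuclei, which have few long-range axons, made up 1.38% ± 0.619 in DMS and 1.82% ± 0.405 in MD libraries (exact permutation p = 0.314, adjusted p = 0.629). Between dorsal and ventral libraries the exact permutation p lay between 0.6 and 0.914 over the 5 classes, in a test whose spread includes the difference between the targets. L5 PT-like nuclei, for example, made up 37.6% ± 31.5 of the dorsal and 45.3% ± 31.0 of the ventral glutamatergic nuclei. Compared within target and sex, the dorsal library had the lower L5 PT-like share in 4 of 4 pairs (means of 10.99% and 19.4% in the DMS and 64.2% and 71.2% in the MD groups, dorsal first). An exact permutation test over the 36 assignments within targets, chosen after the shares were seen, gave p = 0.278 for these nuclei. For the 5 classes this exact permutation test gave p between 0.222 and 0.833, where the smallest possible p is 0.0556, so it could not pass a threshold of 0.05. The sign of the dorsal minus ventral difference of L5 PT-like and of L6 IT-like nuclei turned when the nuclei were clustered more finely (1.04 and -2.17 percentage points). The shares describe nuclei after fluorescence-guided dissection and a sort, and not the composition of the tissue.

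**Figure D1:**
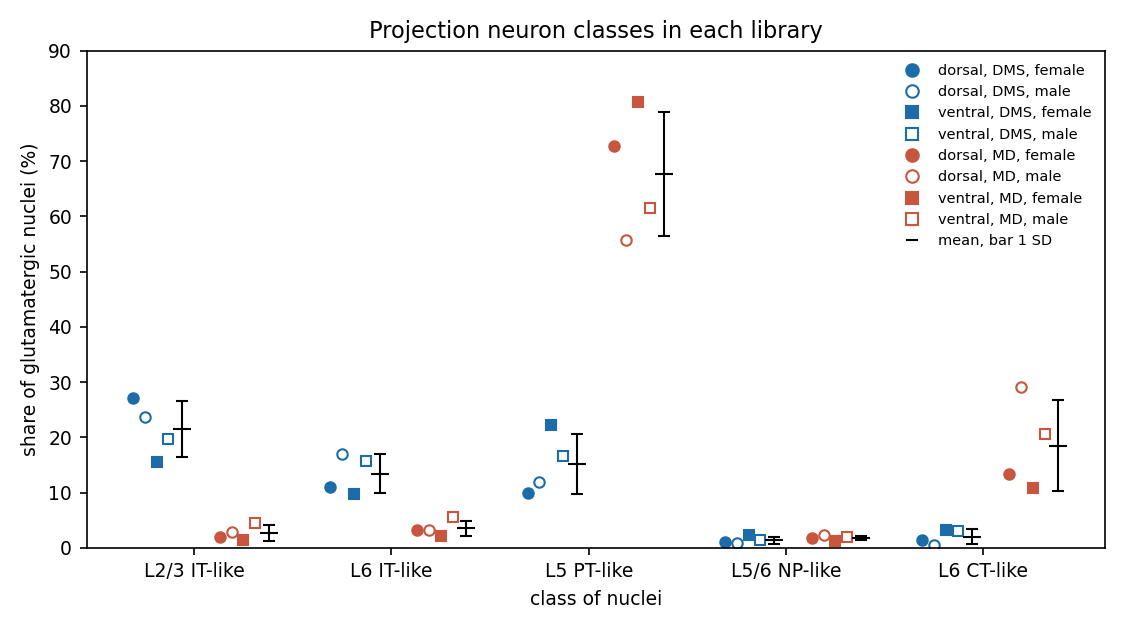
Share of glutamatergic nuclei (y axis, percent) in 5 classes (x axis) for each of the 8 libraries, coloured by injection target, with circles for dorsal and squares for ventral tissue and open symbols for males; black bars give the mean and 1 SD of 4 libraries. The MD libraries lie between 55.8 and 80.8% for L5 PT-like nuclei and the DMS libraries between 9.99 and 22.2%.

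The comparison of DMS with MD libraries within a class asks whether nuclei of the same class differ between libraries of the 2 targets. With no reporter sequence among the features and the gate of the sort not settled, labelled nuclei cannot be told from unlabelled ones. In L6 CT-like nuclei, the genes that were higher in DMS libraries included single genes of potassium channel subunits, axon guidance and cadherins. Kcnab1, an auxiliary subunit of voltage-gated potassium channels (ENSMUSG00000027827, GRCm38 chromosome 3, 65109384 to 65378223), rose by a log2 fold change of 2.24 ± 0.12 (SE; 314 ± 93.8 CPM in DMS and 67.2 ± 10.1 CPM in MD libraries, mean ± SD, n = 4 each; edgeR adjusted p = 7.23e-15). Kcnc2, a Kv3 channel of fast-spiking neurons, rose by 1.78 ± 0.21 and Kcnip4, a channel-interacting protein, by 1.41 ± 0.09. Axon guidance genes were not called as a list in this class (10 of 40 called higher and 5 lower, camera adjusted p = 0.602). Among them, the netrin receptor Unc5d rose by 1.96 ± 0.20, the ephrin Efna5 by 1.40 ± 0.17 and the Slit receptor Robo2 by 1.01 ± 0.11. Among cadherins, Cdh10 rose by 1.72 ± 0.12, Cdh9 by 1.07 ± 0.14 and Pcdh15 by 0.90 ± 0.11 (adjusted p between 2.67e-12 and 4.99e-06 for these 8 genes). CPM are the summed counts of a class scaled to its total in the library after TMM normalization. The glutamate receptor-like gene Grid1 was lower in DMS libraries by -0.54 ± 0.09 (adjusted p = 2.05e-04).

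Genes that mark other cortical layers were also higher in the L6 CT-like nuclei of DMS libraries. They included Cux2 (2.31 ± 0.28), a transcription factor of upper layers, Il1rapl2 (1.85 ± 0.16), Synpr (2.57 ± 0.45) and Svil (2.02 ± 0.26). Of the CT markers, which also served to name the class, Zfpm2 (-0.67 ± 0.09), Foxp2 (-0.49 ± 0.10), Syt6 (-0.53 ± 0.12) and Hs3st4 (-0.40 ± 0.10) were lower. The class was built from different clusters in the 2 targets. Cluster 19, in which 29.9% of nuclei were marked as doublets before removal and which was led by Rai14 and Svil, held 28.3% of L6 CT-like nuclei in the dorsal DMS and 36.5% in the ventral DMS group but 2.33% and 3.84% in the MD groups. Cluster 14 held the rest. It made up 0.379% of the 6857 nuclei kept in dorsal DMS replicate 2, which is under the minimum of 30 nuclei applied to the classes. Within cluster 14 alone, 333 of the 835 genes called in the class were called in the same direction and 14 turned. There the rise of Kcnab1 was smaller, at 0.97 ± 0.20 against 2.24 in the class, as was that of Kcnip4, at 0.70 ± 0.14 against 1.41. Kcnc2 was at 1.74 ± 0.30, Unc5d at 1.33 ± 0.37, Robo2 at 0.81 ± 0.13 and Cdh10 at 1.17 ± 0.17, and the adjusted p of these 6 genes lay between 7.47e-05 and 0.0315. Of the 4 CT markers above only Zfpm2 was called in cluster 14 (-0.44 ± 0.10, adjusted p = 0.00683). Foxp2 was at -0.19 ± 0.11, Syt6 at -0.15 ± 0.14 and Hs3st4 at -0.21 ± 0.10 there, with adjusted p between 0.327 and 0.693. The calcium channel subunit gene Cacna2d3, at 1.23 ± 0.15 in the class, was at -0.19 ± 0.25 in cluster 14 (adjusted p = 0.809). Galnt14, at 2.10 ± 0.20, was at 0.29 ± 0.50 (adjusted p = 0.867).

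In L2/3 IT-like nuclei, the genes that were lower in DMS than in MD libraries included single genes of cadherins and axon guidance. The protocadherin Pcdh11x fell by 1.79 on the log2 scale (SE 0.22; 47.3 ± 26.2 against 156 ± 91.7 CPM, adjusted p = 9.63e-06). The transcription factor gene Tox fell by 1.48 (SE 0.18; adjusted p = 5.29e-06) and the netrin receptor Dcc fell by 1.21 (SE 0.14; 113 ± 24.2 against 271 ± 111 CPM, adjusted p = 2.83e-06). The ephrin receptor Epha7 (-0.79 ± 0.13) was lower too. The axon guidance genes were not called as a list (8 of 44 called lower and none higher, camera adjusted p = 0.0764). With finer clustering the class fell mostly in 2 clusters, and that led by Cux2 and Ccbe1 held 34.8, 31.4, 10.9 and 18.0% of it in the DMS libraries but 1.69 to 3.43% in the MD libraries, so the make-up of the class differed between the targets. Cnbd1 was the gene with the largest rise, at 18.3 ± 2.55 CPM in DMS and 0.355 ± 0.710 CPM in MD libraries, where 3 of 4 libraries had no count. The proprotein convertase gene Pcsk5 was lower in L6 IT-like nuclei of DMS libraries (-1.36 ± 0.17, adjusted p = 1.19e-04), as was the kappa opioid receptor gene Oprk1 (-1.69 ± 0.33; adjusted p = 0.00431). The glypican Gpc5 was higher (1.62 ± 0.24, adjusted p = 5.13e-04). The make-up of the L6 IT-like class differed between the targets too. A finer cluster led by Sema3e and Cdh9 held 24.5, 27.2, 60.4 and 46.9% of it in DMS and 49.4, 65.3, 87.5 and 79.9% in MD libraries. The call of Oprk1 was lost without dorsal DMS replicate 2 or dorsal MD replicate 2, and those of Oprk1 and Gpc5 with finer clustering.

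In L5 PT-like nuclei the genes called were mostly higher in DMS libraries. The membrane mucin gene Muc15 rose by 1.46 ± 0.12, Hacd4, a gene of fatty acid elongation, by 0.88 ± 0.09, the serotonin receptor Htr2b by 0.52 ± 0.08 and the metabotropic glutamate receptor Grm3 by 0.44 ± 0.07 (adjusted p between 7.21e-05 and 0.00155). The PACAP receptor Adcyap1r1 rose by 2.15 ± 0.30 from a low level (3.97 ± 0.746 against 0.874 ± 0.306 CPM; adjusted p = 7.47e-04). In L5/6 NP-like nuclei the receptor phosphatase gene Ptprk (2.72 ± 0.37, adjusted p = 3.49e-05) and Man1c1, a mannosidase of the Golgi (2.65 ± 0.54, adjusted p = 0.00470), were higher in DMS libraries and Zfpm2 lower (-1.10 ± 0.15, adjusted p = 4.31e-05). The call of Man1c1 was lost without dorsal MD replicate 1. A finer cluster of which 46.4% of nuclei were marked as doublets before removal held 28.6, 14.5, 27.3 and 10.9% of the NP-like class in DMS and 5.202, 7.32, 14.8 and 7.07% in MD libraries.

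Over all genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 399 genes between DMS and MD libraries in L2/3 IT-like (251 higher and 148 lower in DMS) and 392 in L6 IT-like nuclei (264 and 128). There were 794 in L5 PT-like (688 and 106), 143 in L5/6 NP-like (122 and 21) and 835 in L6 CT-like nuclei (620 and 215). GABAergic interneurons of the same libraries, most of which have local axons, also differed. In them 116 genes were higher and 13 lower in DMS libraries. Over the genes called higher in DMS libraries, the median ratio of the CPM difference in GABAergic nuclei to that in the class was 0.998 in L5 PT-like nuclei. It was 0.662 in L2/3 IT-like, 0.700 in L6 IT-like, 0.67 in L5/6 NP-like and 0.565 in L6 CT-like nuclei. For the same genes the ratio in astrocytes was lower in every class, between 0.2496 in L5/6 NP-like and 0.5742 in L5 PT-like nuclei. In GABAergic clusters 8, 12 and 31, 10.72, 11.891 and 12.721% of nuclei were marked as doublets before removal, against 2.356% in the astrocyte cluster. Whether doublets raised the GABAergic ratios was not tested. A rise from free RNA was therefore not excluded in any class, though astrocytes showed less of the rise than GABAergic nuclei. Over the genes called higher in MD libraries the GABAergic ratio lay between 0.108 in L6 CT-like and 0.402 in L5 PT-like nuclei. Of the genes called in a projection class and also tested in GABAergic nuclei, 87.1% in L2/3 IT-like, 88.8% in L6 IT-like, 92.4% in L5 PT-like, 92.1% in L5/6 NP-like and 73.7% in L6 CT-like nuclei had the same sign there, against 58.9 to 63.8% of all genes tested. Genes called in the class whose change also differed from that of GABAergic nuclei numbered 43 in L2/3 IT-like, 19 in L6 IT-like, 28 in L5 PT-like, 5 in L5/6 NP-like and 158 in L6 CT-like nuclei. Of the 158 in L6 CT-like nuclei 72 were also called in cluster 14 alone, and of the 28 in L5 PT-like nuclei 17, 15 and 13 in clusters 6, 7 and 13 alone. Pcdh11x, Tox, Dcc, Pcsk5, Gpc5, Adcyap1r1, Man1c1, Grid1, Kcnab1, Kcnc2, Kcnip4, Unc5d, Efna5, Robo2, Cdh10, Cdh9, Pcdh15, Cux2, Il1rapl2, Synpr and Svil were among the genes that differed from GABAergic nuclei (adjusted p of the difference up to 0.0471). Muc15, Hacd4, Htr2b, Grm3, Ptprk in NP-like nuclei, Epha7, Oprk1 and Zfpm2 were not among them (adjusted p of at least 0.217). In simulated data this test recovered at most 16.9% of 1.5-fold changes, so it cannot show that a small change is shared with GABAergic nuclei. With the second deposited matrix the counts were 244 in L2/3 IT-like, 242 in L6 IT-like, 385 in L5 PT-like and 90 in L5/6 NP-like nuclei. With 1 library left out they ranged from 237 (without ventral DMS replicate 2) to 428 in L2/3 IT-like nuclei. They ranged from 171 to 398 in L6 IT-like, from 324 to 1027 in L5 PT-like and from 450 to 905 in L6 CT-like nuclei, the lowest of these 3 each without ventral MD replicate 2. In L5/6 NP-like nuclei they ranged from 55 (without dorsal MD replicate 1) to 161.

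**Figure D2:**
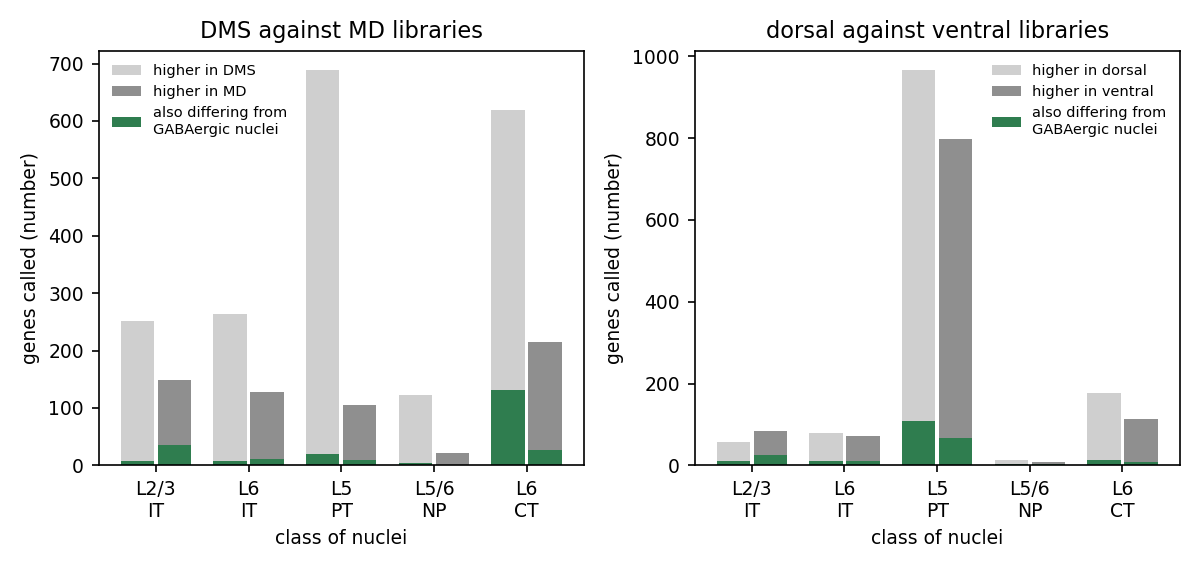
Number of genes called by edgeR (y axis) in each class of nuclei (x axis) between DMS and MD libraries (left) and between dorsal and ventral libraries (right), in pairs of bars for the 2 directions; the green part of a bar is the genes whose change also differed from that in GABAergic nuclei of the same libraries. In L5 PT-like nuclei 28 of 794 and 175 of 1762 genes were of that kind.

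Among the genes called in the same direction in all 5 classes between DMS and MD libraries were Fgfr2, a fibroblast growth factor receptor, and 4 noncoding genes, Sorbs2os, Pcsk2os2, Nell1os and A330015K06Rik. These 5 came first by the rule for named genes, and the full number of genes called in all 5 classes was not counted. The log2 fold changes of the 5 named genes in L2/3 IT-like nuclei were 0.56, 0.79, 0.88, 1.89 and 0.96. In GABAergic nuclei they were 0.44, 1.19, 2.01, 1.07 and 0.74. A330015K06Rik lies antisense within Kcnab1 (chromosome 3, 65133060 to 65302685) and rose with it in L6 CT-like nuclei, by 3.37 ± 0.12. Whether the counting used strand is not given in the sources used here, so reads of these antisense genes and of their hosts cannot be told apart with certainty.

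Of the gene lists fixed in advance, the transcripts encoded by the mitochondrial genome were lower in DMS libraries in all 5 classes (limma camera, preset correlation). In L6 CT-like nuclei 5 of 10 were called lower and none higher, or 8 lower when adjusted over the list alone. For the list this gave adjusted p = 0.00236, or adjusted p = 0.541 with an estimated correlation. Of 12 in L5 PT-like nuclei, 6 were called lower, or 9 adjusted over the list alone. The test of the list gave adjusted p = 3.54e-05, or adjusted p = 0.980 with an estimated correlation. Mt-Co3 and mt-Co2, subunits of cytochrome c oxidase, were at -0.84 ± 0.15 and -0.77 ± 0.15 in L5 PT-like nuclei, and at -0.96 and -1.49 in GABAergic nuclei. Of 12 in L2/3 IT-like nuclei, 3 were called lower, or 7 adjusted over the list alone. There the list had adjusted p = 3.08e-04, or adjusted p = 0.667 with an estimated correlation. Of 10 in L6 IT-like nuclei, 4 were called lower, or 8 adjusted over the list alone. In this class it had adjusted p = 0.00109, or adjusted p = 0.684 with an estimated correlation. Of 5 in L5/6 NP-like nuclei, 0 were called, or 1 lower adjusted over the list alone. Here it had adjusted p = 0.0475, or adjusted p = 0.907 with an estimated correlation.

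With the preset correlation only, cadherins and protocadherins were called lower in DMS libraries as a list in L2/3 IT-like and L6 IT-like nuclei. In L6 CT-like nuclei these genes were called higher as a list, also with the preset correlation only. Of 22 in L2/3 IT-like nuclei, 7 were called lower in DMS libraries and none higher, or 12 lower and 1 higher adjusted over the list alone. The list had adjusted p = 1.65e-06, or adjusted p = 0.667 with an estimated correlation. Of 20 in L6 IT-like nuclei, 5 were called lower, or 12 adjusted over the list alone. That gave adjusted p = 0.00136, or adjusted p = 0.684 with an estimated correlation. Of 21 in L6 CT-like nuclei, 8 were called higher and none lower, or 9 higher and 4 lower adjusted over the list alone. Their list had adjusted p = 0.00236, or adjusted p = 0.541 with an estimated correlation. The difference between the classes was not tested.

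Immediate early genes, which respond to neuronal activity, were shifted higher in DMS libraries in 2 classes. None of 27 was called in L2/3 IT-like nuclei, also adjusted over the list alone. As a list they had adjusted p = 0.0144, or adjusted p = 0.892 with an estimated correlation. In L5 PT-like nuclei 1 of 28 was called, the same adjusted over the list alone. Their test gave adjusted p = 0.00537, or adjusted p = 0.980 with an estimated correlation. Cortical areal patterning genes, Epha7 among them, were lower in L2/3 IT-like nuclei, with 2 of 22 called, or 5 adjusted over the list alone. These had adjusted p = 0.0284, or adjusted p = 0.667 with an estimated correlation. Axon guidance genes were lower in L6 IT-like nuclei, with 6 of 42 called, or 12 lower and 4 higher adjusted over the list alone. They had adjusted p = 0.0264, or adjusted p = 0.684 with an estimated correlation. Ionotropic glutamate receptors were lower in the same class, with 3 of 16 called, or 5 adjusted over the list alone. For them the test gave adjusted p = 0.0250, or adjusted p = 0.684 with an estimated correlation. L6 IT markers were lower too, with 1 of 4 called, or 2 adjusted over the list alone. The markers had adjusted p = 0.0250, or adjusted p = 0.684 with an estimated correlation. The make-up of the L6 IT-like class in finer clusters differed between the targets, and the list tests cannot tell this from a change within cells.

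Voltage-gated potassium channel genes were higher in L6 CT-like nuclei of DMS libraries, with 5 of 31 called higher and 2 lower, the same adjusted over the list alone. The channels had adjusted p = 0.0242, or adjusted p = 0.541 with an estimated correlation. Neuropeptides and their receptors were higher as well, with 2 of 10 called, or 7 higher and 1 lower adjusted over the list alone, Crhr1 at 2.24 ± 0.44 among them. This list had adjusted p = 0.0223, or adjusted p = 0.541 with an estimated correlation. Markers of L2/3 IT neurons were higher beside them, with 3 of 5 called, the same adjusted over the list alone. These markers had adjusted p = 0.00697, or adjusted p = 0.541 with an estimated correlation. L5 IT markers were higher, with 2 of 3 called, or 3 adjusted over the list alone. Those had adjusted p = 0.0223, or adjusted p = 0.541 with an estimated correlation. L6 CT markers were lower, with 5 of 6 called, the same adjusted over the list alone. Of these 5 genes, Foxp2, Syt6 and Hs3st4 were not called in cluster 14 alone. The CT markers had adjusted p = 0.00236, or adjusted p = 0.541 with an estimated correlation. Nuclear-encoded genes of oxidative phosphorylation were lower as a list with 0 of 40 called, also adjusted over the list alone. The result was adjusted p = 0.0242, or adjusted p = 0.647 with an estimated correlation. L6 CT markers were lower in L5/6 NP-like nuclei of DMS libraries, with 2 of 4 called, or 4 adjusted over the list alone. In these nuclei the list had adjusted p = 6.92e-04, or adjusted p = 0.907 with an estimated correlation. Microglial markers were higher in L5 PT-like nuclei, with 2 of 5 called, the same adjusted over the list alone. The microglial list had adjusted p = 0.0281, or adjusted p = 0.980 with an estimated correlation.

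The comparison of dorsal with ventral tissue asks which genes differ between the subregions within a class. L5 PT-like nuclei of dorsal tissue were lower in Brinp3, a gene for a secreted neuronal protein (ENSMUSG00000035131, GRCm38 chromosome 1, 146494760 to 146902472), by 1.78 on the log2 scale (SE 0.09, n = 4 each; edgeR adjusted p = 6.94e-08). It was at 39.1 to 61.4 CPM in dorsal and 158.5 to 180.3 CPM in ventral libraries. The protein kinase gene Prkd1 fell by 1.64 (SE 0.10; adjusted p = 2.30e-07). The potassium channel gene Kcnc2 (ENSMUSG00000035681, GRCm38 chromosome 10, 112271121 to 112467024) was higher by 2.19 ± 0.27 (27.9 ± 5.95 against 7.05 ± 4.59 CPM, adjusted p = 1.07e-04). Higher, too, were Lhfp (2.07 ± 0.22, adjusted p = 4.50e-05) and the serotonin receptor Htr7 (2.17 ± 0.38, adjusted p = 0.00194). Type II cadherins split, with Cdh7 (-0.98 ± 0.10), Cdh9 (-1.12 ± 0.14) and Cdh10 (-0.61 ± 0.07) lower and Cdh8 (0.94 ± 0.12) higher in dorsal libraries. The ephrin receptor Ephb1 was higher (0.80 ± 0.09). Each of these 10 genes also differed from GABAergic nuclei in its change (adjusted p up to 0.0284).

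Single receptor genes were called in either direction between the subregions in L5 PT-like nuclei. The glutamate receptor genes Gria4 (-0.55 ± 0.08) and Grik2 (-0.65 ± 0.09), the GABA receptor gene Gabra2 (-0.54 ± 0.08) and the serotonin receptor Htr4 (-0.53 ± 0.10) were lower in dorsal libraries. Higher were the noradrenaline receptors Adra1b (1.42 ± 0.26) and Adrb1 (0.44 ± 0.08). Epha6 (-0.79 ± 0.10) and Epha7 (-0.74 ± 0.09) were lower, and the PT marker Slco2a1, a prostaglandin transporter, was higher (1.86 ± 0.16). Different clusters held most of the class in the subregions: clusters 6 and 15 held 31.9% and 25.6% of it in the dorsal DMS and 37.0% and 15.6% in the dorsal MD group. Clusters 7 and 13 held 46.6% and 37.3% in the ventral DMS and 40.6% and 39.9% in the ventral MD group. Prkd1, Cdh7, Cdh8, Cdh10, Ephb1, Epha6, Gria4 and Slco2a1 were called in each of clusters 6, 7 and 13 tested alone, Prkd1 at -1.64 ± 0.27, -1.19 ± 0.12 and -0.79 ± 0.12. Each of these clusters itself held different finer clusters in the subregions. One of them held 10.2 to 32.5% of cluster 7 in dorsal and 47.3 to 77.0% in ventral libraries. Most of the receptor genes were not called in every cluster. Grik2 was called in cluster 13 but not in 6 or 7, Gabra2 in 6 and 13 but not in 7, and Htr4 in 6 but not in 7 or 13 (-0.02 ± 0.12 in cluster 13). Adra1b was called in cluster 7 alone, Adrb1 in 6 alone and Epha7 in 7 and 13 but not in 6. Brinp3, Kcnc2 and Lhfp were called in clusters 6 and 7 but not in cluster 13 (-0.34 ± 0.12, 0.95 ± 0.40 and 0.92 ± 0.33). Cdh9 was lower in clusters 7 and 13 but at 0.11 ± 0.35 in cluster 6. The transcription factor Rorb, at -2.15 ± 0.19 in the class, was called in cluster 13 alone (-2.86 ± 0.22).

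In L2/3 IT-like nuclei, dorsal libraries were lower in Tox (-1.69 ± 0.17, adjusted p = 4.78e-07) and in the contactin Cntn6 (-1.57 ± 0.18, adjusted p = 1.60e-06). They were higher in Nell1 (1.47 ± 0.18, adjusted p = 8.05e-06) and the kainate receptor Grik4 (0.96 ± 0.14, adjusted p = 9.33e-05). The make-up of this class also differed by subregion in the DMS groups. The finer cluster led by Cux2 and Ccbe1 held 34.8 and 31.4% of it in the dorsal DMS and 10.9 and 18.0% in the ventral DMS libraries. It held 2.67 and 2.53% in the dorsal MD and 1.69 and 3.43% in the ventral MD libraries. Dorsal L6 IT-like nuclei were lower in the nuclear factor I genes Nfib (-1.26 ± 0.11, adjusted p = 1.94e-06) and Nfia (-1.24 ± 0.12, adjusted p = 4.13e-06) and in the semaphorin Sema3e (-0.99 ± 0.10, adjusted p = 1.20e-05). Sema3e leads a finer cluster that held 24.5, 27.2, 49.4 and 65.3% of the L6 IT-like class in the dorsal DMS and MD libraries and 60.4, 46.9, 87.5 and 79.9% in the ventral ones. The adhesion molecule Alcam was higher (1.33 ± 0.27, adjusted p = 0.00931), whose call was lost without ventral DMS replicate 1 or ventral MD replicate 2. In L5/6 NP-like nuclei the Wnt receptor Ror1 was lower (-2.55 ± 0.37; 11.8 ± 4.42 against 72.4 ± 21.8 CPM, adjusted p = 2.60e-04). The vesicle priming gene Unc13c was higher (2.52 ± 0.28; 121 ± 13.6 against 21.0 ± 6.23 CPM, adjusted p = 2.13e-06). In L6 CT-like nuclei Spag16 (-2.04 ± 0.22), the imprinted gene Nnat (-1.21 ± 0.13) and Vwc2 (-1.23 ± 0.21) were lower, and Kcnc2 (1.54 ± 0.20), Nell1 (1.49 ± 0.25) and the NMDA receptor subunit Grin2a (0.57 ± 0.09) higher. Tox, Cntn6, Nell1, Nfib, Sema3e, Alcam, Ror1, Unc13c, Vwc2 and Kcnc2 also differed from GABAergic nuclei in these classes (adjusted p up to 0.0341). Grik4, Nfia, Nnat, Spag16 and Grin2a did not pass that test (adjusted p of at least 0.307).

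**Figure D3:**
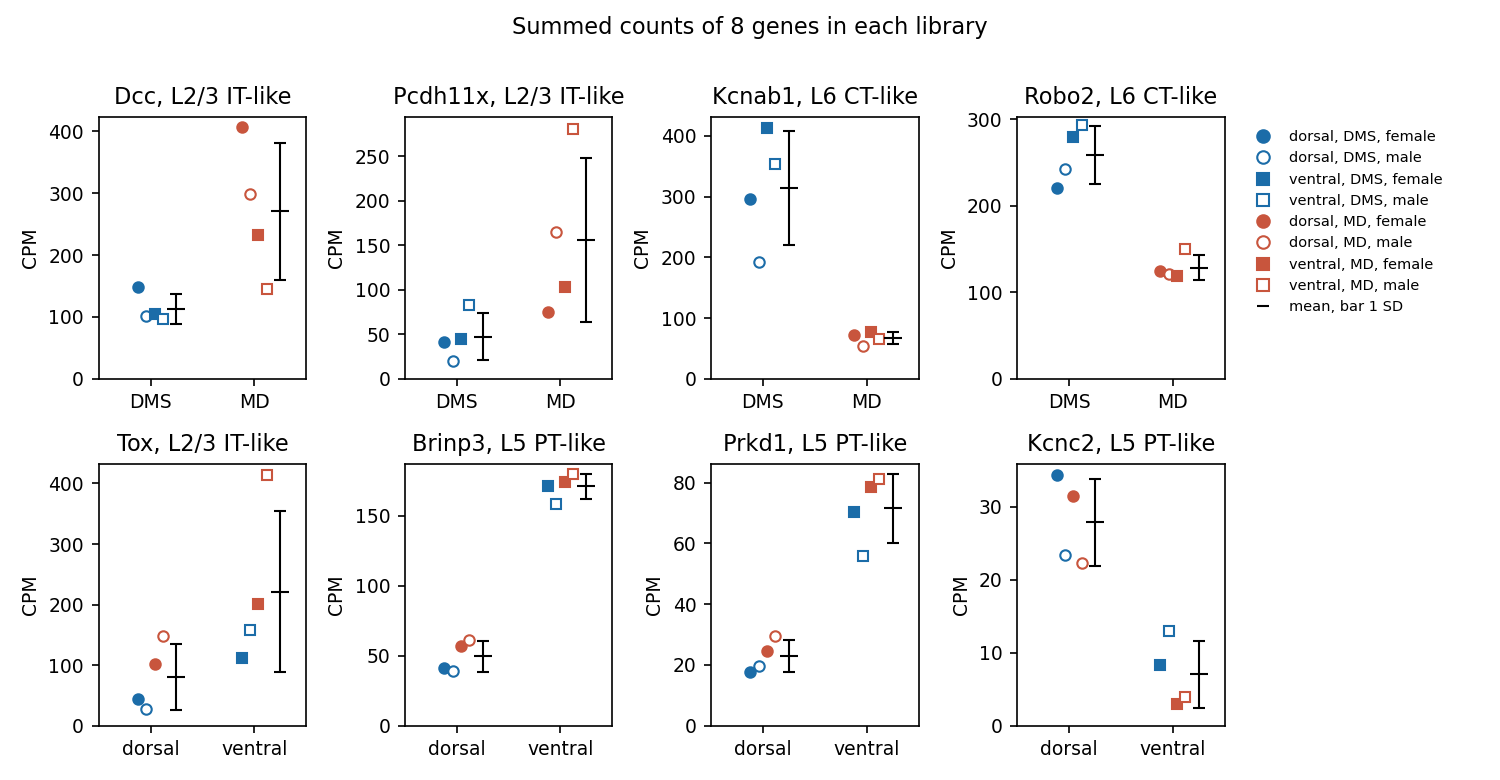
Counts summed over the nuclei of a class, in CPM (y axis), for 8 genes in each library, grouped by target (top row, left panels for L2/3 IT-like and right panels for L6 CT-like nuclei) or by subregion (bottom row, Tox in L2/3 IT-like and the others in L5 PT-like nuclei); colours mark the target, circles dorsal and squares ventral tissue, open symbols males, and black bars the mean and 1 SD of 4 libraries. Brinp3 lies between 39.1 and 61.4 CPM in dorsal and between 158.5 and 180.3 CPM in ventral libraries.

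Ntm, an adhesion molecule of the IgLON family, was higher in dorsal libraries in all 5 classes, by 0.66 in L5/6 NP-like to 0.95 in L6 CT-like nuclei, and in GABAergic nuclei by 0.61. Nell1 and the tetraspanin Tspan5 were higher and the adhesion molecule Chl1 and Nfia lower in dorsal libraries in 4 of the 5 classes. Nell1 was at 0.03 in GABAergic nuclei (adjusted p = 0.974), where Tspan5 was at 0.63. Between dorsal and ventral libraries 142 genes were called in L2/3 IT-like (58 higher and 84 lower in dorsal) and 152 in L6 IT-like nuclei (80 and 72). There were 1762 in L5 PT-like (965 and 797), 20 in L5/6 NP-like (13 and 7) and 291 in L6 CT-like nuclei (178 and 113). GABAergic nuclei had 125 calls, and 36, 21, 175, 7 and 19 genes in the 5 classes, in the same order, were called and also differed from GABAergic nuclei. Of the 175 in L5 PT-like nuclei 69, 56 and 80 were also called in clusters 6, 7 and 13 alone, and of the 19 in L6 CT-like nuclei 13 in cluster 14 alone. GABAergic cluster 31, led by Ano1 and Col25a1, was seen in ventral libraries only (0.19 to 1.374% of kept nuclei), so the composition of this comparison population also differed between the subregions. With the second deposited matrix the counts were 34, 51, 884, 7 and 95 in the 5 classes. Without the replicate block that sex forms in the model, 8 genes were called in L5/6 NP-like and 117 in L6 CT-like nuclei. With 1 library left out the counts ranged from 38 to 246 in L2/3 IT-like and from 34 to 174 in L6 IT-like nuclei, both lowest without ventral DMS replicate 1. They ranged from 689 (without dorsal MD replicate 1) to 2476 in L5 PT-like nuclei. The range was from 2 to 41 in L5/6 NP-like and from 103 to 337 in L6 CT-like nuclei, both lowest without ventral MD replicate 2.

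Of the 27 calls of lists over all contrasts, 7 held with each of the 8 libraries left out. These were cadherins and protocadherins in L2/3 IT-like and L6 CT-like, mitochondrially encoded transcripts in L5 PT-like and L6 CT-like and L6 CT markers in L5/6 NP-like and L6 CT-like nuclei between DMS and MD, and the interferon and innate immune genes between dorsal and ventral L6 CT-like nuclei. Every other call was lost without at least 1 library, and the least stable held in 3 of the 8 fits. Among the lists, 2 were called between dorsal and ventral libraries, both in L6 CT-like nuclei. Interferon and innate immune genes were lower in dorsal libraries, with 2 of 7 called, or 4 adjusted over the list alone, Ifi27 at -0.82 ± 0.22 among them. The immune list had adjusted p = 0.00239, or adjusted p = 0.972 with an estimated correlation. Voltage-gated potassium channels were higher, with 4 of 31 called higher and 1 lower, or 8 and 2 adjusted over the list alone. As a list the channels had adjusted p = 0.00359, or adjusted p = 0.972 with an estimated correlation. Kcnc2 was higher and the calcium-activated channel gene Kcnn3 lower (-0.91 ± 0.16), which was at -1.51 in GABAergic nuclei.

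Whether the difference between targets depends on the subregion was tested as an interaction. In L6 IT-like nuclei 41 genes were called, 39 of them with a DMS minus MD difference that was lower in dorsal than in ventral tissue. Ccbe1, a secreted factor that also marks upper layers, was at 100.6 and 117 CPM in the dorsal DMS and at 197 and 261 CPM in the dorsal MD libraries, but at 107 and 104 CPM in the ventral DMS and at 19.8 and 42.6 CPM in the ventral MD libraries (interaction log2 -2.64 ± 0.28, edgeR adjusted p = 9.49e-05). The relaxin receptor Rxfp1 (-2.20 ± 0.25, adjusted p = 1.05e-04) and Il1rapl2 (-2.02 ± 0.23, adjusted p = 1.05e-04) had the same sign. Finer clustering split the class, and a cluster led by Rxfp1 and Ccbe1 held 52.2 and 49.6% of it in the dorsal DMS, 39.0 and 30.7% in the dorsal MD, 17.3 and 27.0% in the ventral DMS and 4.55 and 8.48% in the ventral MD libraries. The L6 IT-like class of the finer clustering was without that cluster, and there Ccbe1 was at -2.46, Rxfp1 at -1.87 and Il1rapl2 at -1.79, each called. In L2/3 IT-like nuclei 17 genes were called, all lower, led by the noncoding genes Gm32647 (-2.52 ± 0.32, adjusted p = 8.87e-06) and Gm15398 (-1.86 ± 0.25, adjusted p = 1.87e-05). The L2/3 IT-like class of the finer clustering was a changed set of nuclei, with a cluster of 918 nuclei from outside this class. Gm32647 lost its call with the second matrix and without ventral MD replicate 2, and Gm15398 with finer clustering. No gene was called by edgeR in L5 PT-like, L5/6 NP-like or L6 CT-like nuclei, where 930, 218 and 597 genes had an unadjusted p under 0.05 and DESeq2 called 0, 0 and 0. The additive fits of these classes tested 16491, 5863 and 10779 genes, and chance puts a share of about 0.05 under that threshold. Such counts alone therefore show no difference. The count in L2/3 IT-like nuclei fell to 2 without ventral MD replicate 2, 2 with finer clustering, 1 with the second deposited matrix and 7 without the replicate block, and rose to 77 without dorsal DMS replicate 1. In the 3 classes without a call, the highest counts with 1 library left out were 92 in L5 PT-like and 5 in L5/6 NP-like nuclei (without dorsal DMS replicate 1) and 11 in L6 CT-like nuclei (without dorsal MD replicate 2), and without a gene filter the counts were 54, 1 and 10. In L6 IT-like nuclei the count ranged from 15 without ventral MD replicate 1 to 60 with 1 library left out and was 10 with the second matrix.

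Female and male libraries differed in the genes of the sex chromosomes. Xist, the noncoding RNA of the inactive X chromosome, was at 782 ± 242 CPM in female and 0.0881 ± 0.176 CPM in male libraries in L5 PT-like nuclei (n = 4 each). The Y-linked genes Uty and Eif2s3y were at 0.162 ± 0.140 and 0.0422 ± 0.0642 CPM in female and 120.2 ± 25.4 and 100.2 ± 18.7 CPM in male libraries. In every class these genes separated the 4 libraries labelled female from the 4 labelled male, as did Kdm5d and, where tested, Ddx3y. Frmpd4, an X-linked gene for a postsynaptic scaffold protein that was chosen after its values were seen, was lower in female libraries in all 5 classes, from -0.90 ± 0.16 in L2/3 IT-like to -1.12 ± 0.12 in L5/6 NP-like nuclei (adjusted p from 0.00725 to 1.12e-07), and by -1.03 in GABAergic nuclei. In L2/3 IT-like nuclei its call was lost without ventral DMS replicate 2 or ventral MD replicate 1.

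Autosomal genes were called between the sexes in single classes. Chst9, a sulfotransferase gene, was at 0.99 ± 0.20 in L2/3 IT-like, 4933436I20Rik at -1.08 ± 0.19 in L6 IT-like and Gm11290 at 1.06 ± 0.16 in L5 PT-like nuclei. Fkbp2 was at 0.82 ± 0.15 and Gm10800 at -3.19 ± 0.53 in L6 CT-like nuclei (female minus male). Each of these calls was lost with at least 1 library left out. In total 10 genes were called in L2/3 IT-like, 9 in L6 IT-like, 17 in L5 PT-like, 7 in L5/6 NP-like and 22 in L6 CT-like nuclei. These counts ranged from 7 to 30, 7 to 11, 8 to 289, 7 to 19 and 11 to 52 with 1 library left out, the highest in L5 PT-like nuclei without dorsal DMS replicate 2. Mitochondrially encoded transcripts were lower in female libraries as a list in L5 PT-like nuclei, with 0 of 12 called, or 6 adjusted over the list alone. Between the sexes it had adjusted p = 1.79e-04, or adjusted p = 0.880 with an estimated correlation. In L6 IT-like nuclei 0 of 10 were called, or 2 adjusted over the list alone. This class had adjusted p = 0.0385, or adjusted p = 0.936 with an estimated correlation. L6 CT markers were lower in L5/6 NP-like nuclei of female libraries, with 0 of 4 called, or 4 adjusted over the list alone. For these the list had adjusted p = 0.00874, or adjusted p = 0.992 with an estimated correlation.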

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

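The tests of the 35 splits of the libraries and of the L5 PT-like (finer ones included) and L6 CT-like clusters, the fits against GABAergic nuclei and those in single clusters were chosen only after the results were seen. Cluster 29, led by Ebf1, Rnf220, Klhl1 and Tcf7l2, made up 11.4% of kept nuclei in ventral MD replicate 2 and at most 0.087% elsewhere, and brought its share of nuclei without a class name to 13.2%, far from the other MD and from the other ventral libraries. Astrocytes made up 1.82% of dorsal MD replicate 2, apart from the other MD libraries. Oligodendrocyte precursors made up 0.102% of dorsal DMS replicate 2, apart from the other DMS libraries. Doublet-rich clusters made up 5.02% of ventral DMS replicate 1, apart from the other ventral libraries. Ependymal nuclei made up 0.130% of ventral MD replicate 1 among MD libraries and 0.0160% of dorsal MD replicate 2 among dorsal libraries, where the others had 0. In all, 7 of the 76 groups of libraries examined held a value this far from the rest, where chance gives about 3.8. This excess was not tested, because the groups share libraries and the 13.2% counts in both the MD and the ventral group. The precursor value rests on 7 nuclei and the ependymal values on 6 and 1.

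The DMS minus MD difference itself differed between dorsal and ventral tissue in L6 IT-like nuclei for 41 genes, among them Ccbe1 (-2.64), Rxfp1 (-2.20) and Il1rapl2 (-2.02), and in L2/3 IT-like nuclei for 17 genes, among them Gm32647 (-2.52) and Gm15398 (-1.86), all by the interaction test. Ccbe1, Rxfp1 and Il1rapl2 passed the threshold in every alternative run that tested them. Gm32647 did not pass with the second matrix (adjusted p = 0.0639) or without ventral MD replicate 2 (0.189), and Gm15398 did not at resolution 2 (0.428).

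The first pattern is the 620 genes called higher in L6 CT-like nuclei of DMS libraries, where IT nuclei are the majority. Different shares of clusters 14 and 19 alone would leave no change within cluster 14. There the median ratio of the log2 change of these genes to that in the class was 0.855 (0.842 to 0.874 with each library left out). Shares are therefore not the whole cause, though the genes were called partly in these same nuclei, which can raise the ratio. Single genes lost more, such as Kcnab1 from 2.24 to 0.97. Free RNA from the dominant nuclei could raise the genes in every cell type. The median ratio of the CPM difference over the 620 genes in GABAergic nuclei to that in L6 CT-like nuclei was 0.565 (0.548 to 0.591). This met the bound of at least 0.5 that was written down before the test for free RNA as the cause. In astrocytes the ratio was 0.252, which lies below 0.5. Of the genes 131 also differed from GABAergic nuclei, but that test compares log2 changes and not CPM differences, so it cannot exclude free RNA. Free RNA therefore stays open for the set. Doublets with IT nuclei could also raise these genes and cannot be told apart here. The median change in nuclei with lower doublet scores was 0.810 of that in nuclei with higher scores (0.786 to 0.820). That lies on both sides of the bound of 0.8 written down before the doublet test. A difference between CT neurons that reach the striatum and those that do not stays open and was not tested. Labelled nuclei cannot be told from unlabelled ones, so whether the L6 CT-like nuclei of DMS libraries were labelled is not known.

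The second pattern is the lower level of mitochondrially encoded transcripts in DMS libraries. A library-wide amount of cytoplasmic RNA carried along with the nuclei may account for it, since the median log2 difference was -0.82 in GABAergic nuclei (-0.89 to -0.68 with each library left out), against -0.48 in L5 PT-like and -0.87 in L6 CT-like nuclei. It was -0.79 in oligodendrocytes and -0.58 in astrocytes. An effect of the target on mitochondrial transcripts in projection neurons was not separately tested.

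The third pattern is the number of genes called between dorsal and ventral L5 PT-like nuclei. Different shares of clusters 6, 7 and 13 alone would leave no change within them. The median ratio of the genes' log2 change within single clusters to that in the class was 0.649 in cluster 7 and 0.811 in cluster 6. It lay between 0.577 and 0.711 within the 3 finer clusters that could be tested (0.506 at the lowest with each library left out). These values lie above a bound of 0.5 that was chosen after they were seen. The finer clusters tested, 17, 28 and 7, came mainly from clusters 13 and 7. The genes were called in these same nuclei, which can raise the ratios. Different shares of the clusters tested are thus not the whole cause, but those of the untested finer clusters were not excluded. Part of the change may go with the make-up, since the ratios are below 1 and most finer clusters had too few nuclei to test, and single genes depart further, such as Etv1 at -0.38 in the class and 0.53 in cluster 6. Free RNA that differs between subregions was not excluded, since 80.4% of the called genes had the same sign in GABAergic nuclei, against 64.2% of all genes tested. A difference between the subregions in the neurons themselves stays open as a hypothesis.

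For DMS against MD, only the real split, 1 of the 35 splits of the 8 libraries into 4 and 4, called as many genes in each class. The counts were 399 in L2/3 IT-like (highest other split 33), 392 in L6 IT-like (7), 794 in L5 PT-like (757), 143 in L5/6 NP-like (5) and 835 in L6 CT-like nuclei (26). A share of 1 in 35 is under 0.05 for each count taken singly, but it is the smallest possible and was not adjusted over the counts. The fits of the other splits also left out the real factor, whose effect then added to their residual spread. The splits therefore show that no other grouping called as many genes, and do not exclude chance. The split with 757 genes follows the subregions. For dorsal against ventral, only the real split called as many in L2/3 IT-like (142, highest other 139), L6 IT-like (152, 146) and L5 PT-like nuclei (1762, 175). The same limits hold there. The margins in L2/3 IT-like and L6 IT-like nuclei are narrow, and without ventral DMS replicate 1 these counts were 38 and 34. As many were called by 2 splits in L5/6 NP-like (20, 81) and L6 CT-like nuclei (291, 515), so there chance cannot be excluded even for a count taken singly. The highest other split is the one by target in each class, which points to that structure of the samples, and the next highest called 14 in L5/6 NP-like and 108 in L6 CT-like nuclei. For female against male, 8 of the 35 splits called as many genes in L2/3 IT-like (10, highest other 382), 5 in L6 IT-like (9, 396), 6 in L5 PT-like (17, 1570), 4 in L5/6 NP-like (7, 110) and 4 in L6 CT-like nuclei (22, 724), so chance cannot be excluded for these counts. Those highest splits follow the target, or in L5 PT-like nuclei the subregion, and point to that structure of the samples.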

How the results depend on the processing

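The difference from GABAergic nuclei, the fits in single clusters, the earlier naming rules and the test of shares within targets were chosen only after the results were seen. Apart from the fits that left out a library, 100 counts of genes stayed within 1.5 times the reported one, 18 were higher and 48 lower, and of the values of named genes 2042 kept their direction and side of the threshold, 365 kept the direction only and 21 reversed. With 1 library left out, 2004 values of named genes kept both, 411 kept the direction only, 1 passed the threshold anew and 17 reversed. RLE normalization moved no count of genes by more than 1.5 times. In a group with 1 library left, that library is assumed to vary like the others. The cause of the changes below was not tested, and each count is followed by the reported one in parentheses.

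With the Wald test of DESeq2, the genes called numbered 227 in L6 IT-like (392) and 41 in L5/6 NP-like (143) nuclei between DMS and MD. There were 66 in L2/3 IT-like (142), 92 in L6 IT-like (152), 13 in L5/6 NP-like (20) and 163 in L6 CT-like (291) nuclei between dorsal and ventral. There were 13 in L6 CT-like (22) nuclei between the sexes. Without a gene filter they numbered 1303 in L5 PT-like (794) nuclei between DMS and MD. There were 228 in L2/3 IT-like (142), 262 in L6 IT-like (152) and 34 in L5/6 NP-like (20) nuclei between dorsal and ventral. There were 29 in L2/3 IT-like (10), 23 in L6 IT-like (9), 114 in L5 PT-like (17), 15 in L5/6 NP-like (7) and 47 in L6 CT-like (22) nuclei between the sexes. There were 32 in L2/3 IT-like (17), 73 in L6 IT-like (41), 54 in L5 PT-like (0), 1 in L5/6 NP-like (0) and 10 in L6 CT-like (0) nuclei for the interaction. With the second deposited matrix they numbered 244 in L2/3 IT-like (399), 242 in L6 IT-like (392), 385 in L5 PT-like (794) and 90 in L5/6 NP-like (143) nuclei between DMS and MD. There were 34 in L2/3 IT-like (142), 51 in L6 IT-like (152), 884 in L5 PT-like (1762), 7 in L5/6 NP-like (20) and 95 in L6 CT-like (291) nuclei between dorsal and ventral. There were 6 in L2/3 IT-like (10), 6 in L5 PT-like (17) and 7 in L6 CT-like (22) nuclei between the sexes. There were 1 in L2/3 IT-like (17) and 10 in L6 IT-like (41) nuclei for the interaction. At resolution 2 the L2/3 IT-like class was a changed set of nuclei, which took in finer cluster 11 (918 nuclei) from outside cluster 1. In dorsal MD replicate 1 finer cluster 11 made up 1.56% of kept nuclei and finer cluster 1 made up 1.77%. With that clustering the genes called numbered 873 in L2/3 IT-like (399) and 184 in L6 IT-like (392) nuclei between DMS and MD. There were 34 in L6 IT-like (152) nuclei between dorsal and ventral. There were 2 in L2/3 IT-like (17), 25 in L6 IT-like (41) and 1 in L6 CT-like (0) nuclei for the interaction. With no replicate block, that is with sex left out of the model, they numbered 8 in L5/6 NP-like (20) and 117 in L6 CT-like (291) nuclei between dorsal and ventral. There were 7 in L2/3 IT-like (17) nuclei for the interaction.

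In cluster 6 alone they numbered 338 in L5 PT-like (794) nuclei between DMS and MD. There were 362 in L5 PT-like (1762) nuclei between dorsal and ventral. There were 9 in L5 PT-like (17) nuclei between the sexes. In cluster 7 alone they numbered 499 in L5 PT-like (794) nuclei between DMS and MD. There were 248 in L5 PT-like (1762) nuclei between dorsal and ventral. There were 2 in L5 PT-like (0) nuclei for the interaction. In cluster 13 alone they numbered 466 in L5 PT-like (794) nuclei between DMS and MD. There were 560 in L5 PT-like (1762) nuclei between dorsal and ventral. There were 1 in L5 PT-like (0) nuclei for the interaction. In cluster 14 alone they numbered 383 in L6 CT-like (835) nuclei between DMS and MD. As a difference from GABAergic nuclei of the same library they numbered 116 in L2/3 IT-like (399), 76 in L6 IT-like (392), 185 in L5 PT-like (794), 7 in L5/6 NP-like (143) and 224 in L6 CT-like (835) nuclei between DMS and MD. There were 81 in L6 IT-like (152), 321 in L5 PT-like (1762) and 69 in L6 CT-like (291) nuclei between dorsal and ventral. There were 0 in L2/3 IT-like (10), 0 in L6 IT-like (9), 3 in L5 PT-like (17) and 0 in L6 CT-like (22) nuclei between the sexes. The counts of 0 between the sexes are from edgeR, with 561, 413 and 409 genes at an unadjusted p under 0.05 in the same order, and DESeq2 was not run for this difference. The genes tested in these classes numbered 13391, 12163 and 10779, and chance puts a share of about 0.05 under that threshold. With an estimated correlation 0 gene lists were called (27), and with 1 library left out 24 to 51, although only 7 of the 27 calls held in all 8 of those fits.

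Values of single genes that reversed, as log2 fold changes, were the following. With the second matrix, Rpl10a was -1.19 between DMS and MD in L2/3 IT-like nuclei. At resolution 2, Rpl10a was 0.0114 between dorsal and ventral in L2/3 IT-like nuclei. With the second matrix, Rpl10a was -0.92 between DMS and MD in L6 IT-like nuclei. With stricter nuclei, Rpl10a was 0.0126 between dorsal and ventral in L6 IT-like nuclei. At resolution 2, Rpl10a was 0.0373 between dorsal and ventral in L6 IT-like nuclei. In cluster 6 alone, Etv1 was 0.53, Pde1b was 0.0201, Cdh9 was 0.11 and Nfia was 0.20 between dorsal and ventral in L5 PT-like nuclei. In cluster 7 alone, Rpl10a was 0.10 between DMS and MD in L5 PT-like nuclei. In cluster 7 alone, Etv1 was 0.15, Pde1b was 0.12, Nfia was 0.0285, Kcnh5 was -0.19, Gap43 was 0.00106, Htr1f was -0.23 and Sv2c was -0.0303 between dorsal and ventral in L5 PT-like nuclei. In cluster 13 alone, Grin3a was -0.0684 and Ndnf was 0.13 between dorsal and ventral in L5 PT-like nuclei. In cluster 14 alone, Cacna2d3 was -0.19 between DMS and MD in L6 CT-like nuclei. In cluster 14 alone, Il1rapl2 was 0.0819 between dorsal and ventral in L6 CT-like nuclei. With 1 library left out, Rpl10a ranged from -0.53 to 0.18 between dorsal and ventral in L2/3 IT-like, -0.23 to 0.30 between DMS and MD in L2/3 IT-like, -0.31 to 0.10 between dorsal and ventral in L6 IT-like, -0.27 to 0.12 between DMS and MD in L5 PT-like, -0.46 to 0.0413 between DMS and MD in L5/6 NP-like and -0.16 to 0.34 between dorsal and ventral in L5/6 NP-like nuclei.

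The dorsal minus ventral difference of shares reversed at resolution 2 to -2.17 percentage points in L6 IT-like and 1.04 in L5 PT-like nuclei, and with 1 library left out it ranged from -0.796 to 7.61 in L2/3 IT-like, -2.45 to 2.83 in L6 IT-like, -19.3 to 4.18 in L5 PT-like and -4.29 to 5.47 in L6 CT-like nuclei. At resolution 2 most of cluster 13 had no class name, and the DMS minus MD difference of the share of unnamed glutamatergic clusters reversed to -15.2. The DMS minus MD differences of the 5 classes kept their direction in every alternative run.

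With 1 library left out, the genes called ranged between DMS and MD from 237 to 428 in L2/3 IT-like, 171 to 398 in L6 IT-like, 324 to 1027 in L5 PT-like, 55 to 161 in L5/6 NP-like and 450 to 905 in L6 CT-like nuclei. They ranged between dorsal and ventral from 38 to 246 in L2/3 IT-like, 34 to 174 in L6 IT-like, 689 to 2476 in L5 PT-like, 2 to 41 in L5/6 NP-like and 103 to 337 in L6 CT-like nuclei. They ranged between the sexes from 7 to 30 in L2/3 IT-like, 7 to 11 in L6 IT-like, 8 to 289 in L5 PT-like, 7 to 19 in L5/6 NP-like and 11 to 52 in L6 CT-like nuclei. They ranged for the interaction from 2 to 77 in L2/3 IT-like, 15 to 60 in L6 IT-like, 0 to 92 in L5 PT-like, 0 to 5 in L5/6 NP-like and 0 to 11 in L6 CT-like nuclei. In some classes few nuclei stand behind a whole library, such as 35 L6 CT-like nuclei in dorsal DMS replicate 2 and 59 L2/3 IT-like nuclei in ventral MD replicate 1. How far this depth limits the counts was not tested.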

Other observations

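All tests in this part are descriptions of clusters seen after the data were examined. Nuclei outside the comparisons of the report differed between libraries. Cluster 31, a GABAergic cluster led by Ano1, Col25a1 and Sox1ot (247 nuclei), was absent from the dorsal libraries and made up 1.374, 0.190, 0.587 and 1.057% of kept nuclei in ventral DMS replicates 1 and 2 and ventral MD replicates 1 and 2. Cluster 24, with the markers of striatal projection neurons Drd2, Rgs9 and Rarb (361 nuclei), made up 0.443 to 1.661% of ventral and at most 0.080% of dorsal libraries.

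The IT clusters without a resolved layer also parted by subregion among DMS libraries. Cluster 3, led by Mir670hg, Fstl4 and Cux2 (4760 nuclei), made up 18.3 and 20.2% of kept nuclei in the dorsal DMS libraries and 5.65 and 11.5% in the ventral DMS libraries. Cluster 16, led by Zfp804b, Nell1os, Sema3e and Nell1 (2887 nuclei), made up 2.14 and 2.84% in the dorsal DMS and 13.6 and 8.09% in the ventral DMS libraries. Cluster 26, a glutamatergic cluster without a class name led by Cntnap5c, Col23a1 and Nos1 (928 nuclei), made up 7.33% of ventral DMS replicate 1 and at most 1.22% of any other library.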
